A study of Homo sapiens with 12 samples.

How the data were processed

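Gene expression was measured on 12 Affymetrix whole-transcript arrays hybridised with RNA from IMR90 cells, a line of human diploid lung fibroblasts, and from IMR90 cells carrying an inducible ER:RAS construct. Per the labels' protocols, all cells were kept for 7 days in medium with 200 nM 4-hydroxytamoxifen and 0.5% serum, RNA was isolated on columns, and biotinylated material was prepared from 500 ng of total RNA. The co-cultures used porous inserts that separate the cell populations. The pore size is given as 0.2 µm in the design text and as 0.02 µm in the growth protocol, and which applies was not settled.

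The deposited values are log2 signals, 1 per transcript cluster and array. Per the submitters' processing notes, R 2.13.0, RMA and limma were used, with no role or order given. RMA in general subtracts background, normalizes the arrays to each other and summarises the probes of a transcript cluster. The array medians lay between 3.24 and 3.37, no value was missing, and values ran from 1.31 to 11.86. The RMA implementation, the probe annotation behind it and a genome build are not given in the sources used here. After such a normalization a change in total RNA per cell or a shift of most genes in one direction would not be visible, and signals at the bottom of the scale understate fold changes.

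The table held 33297 rows. The annotation of the array gave exactly 1 gene symbol for 19460 rows, several for 1754 and none for 12083. Names were matched to the RefSeq gene table of assembly GRCh38.p14 through the gene number, which succeeded for 19429 of the rows with 1 symbol. No coordinates were used. The tested set was 18417 genes, each represented by its row with the highest mean over the 12 arrays. Of these, 769 genes had more than 1 row, and rows of 1 gene were called in opposite directions for 6 genes in the comparison of RAS cells with parental cells (EIF4A2, LRRFIP1, PDPK1, RPL27A, TPT1 and WNK1) and for 0 genes in the other comparisons. Some genes of the fixed set described below are not reported here. No filter on low signals was applied.

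Groups were taken from the sample labels: parental cells alone, RAS cells alone, parental cells sharing medium with vector cells, and parental cells sharing medium with RAS cells, with 3 arrays each. The labels do not say whether the 3 arrays of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Scan dates and batches were not given in the sources used here. The values themselves show 1 structure that no label records: for every tested gene the mean of the 4 replicate-1 arrays equals that of the other 8, with a largest deviation from the mean of all 12 of 2.08e-05. The variance of this set mean was 5.66e-10 of that expected for independent arrays, and the lowest ratio among the other 80 choices of 1 array per group was 0.565. The deposited values therefore appear to have been centred per set of arrays before deposition, and how this was done is not stated. The number of arrays limits the precision.

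One mean per group was fitted for each gene over all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 8 residual and 5.29 prior degrees of freedom). Contrasts gave the RAS effect (RAS cells alone minus parental cells alone), the co-culture effect (parental cells with RAS cells minus parental cells with vector cells), the effect of vector cells (parental cells with vector cells minus parental cells alone) and the difference between the RAS effect and the co-culture effect. Because of the equal set means, 1 of the 8 residual degrees of freedom carries no spread. In 20 simulated data sets without any change but with that centring, 6.77% to 6.87% of p-values fell below 0.05 in this fit and 5.1% to 5.14% in a fit with a term for the replicate-1 arrays (7 residual degrees of freedom). P-values and errors given here are therefore somewhat too small, and the fit with that term was run beside it. P-values were adjusted by the method of Benjamini and Hochberg within each contrast, and a gene was called at an adjusted p below 0.05. Errors of log2 changes are moderated standard errors from this fit. All adjusted p-values for genes are from limma. The RAS effect and the co-culture effect share no array. The effect of vector cells shares its control with the RAS effect, and its treated group is the control of the co-culture effect. Chance values for the correlation and covariance of these pairs were obtained from 20 simulated data sets without any change. Almost no gene is called in such sets, so their overlap of 0 is no chance value for the overlap of called genes, which is set against independent lists only.

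Gene lists for 25 pathways, functions and cell types were fixed together with the groups, the tests, the alternatives and the rule for named genes before the data were examined, and each was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists within a contrast. The same test with a correlation estimated from the data was run beside it, as was fry. Some lists share members, so shifts of such lists are not independent. With the estimated correlation, the calls that held were RAS-MAPK output genes, secreted proteases and fibroblast identity markers for the RAS effect, RAS-MAPK output genes, contractile genes and fibroblast identity markers for the co-culture effect, growth factors for the effect of vector cells, and secreted proteases for the difference of effects. Gene families of at least 15 members sharing the letters of their symbols, 126 in all, were tested in the same way after the data had been seen. For some lists that were not called, such as TGF-beta family ligands and lamina genes in RAS cells and interferon and NRF2 genes in co-culture, the median, the mean and the direction of the test differed in sign.

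The genes named in the text follow that rule: the 8 largest rises and falls for the RAS and co-culture effects and the 5 largest for the effect of vector cells among called genes whose arrays did not overlap between the groups, the 5 largest rises and falls for the difference of effects, up to 4 members of each list by size of change, and a fixed set of RAS, senescence and secretory genes. Genes outside that rule are named as such.

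The fit was tested on simulated arrays, without the centring described above, with the real means and residual spreads and 200 changed genes among 18417. For the RAS effect it recovered 82.1% of 1.5-fold changes, 98.5% of 2-fold changes and 100% of 4-fold changes, with 8 calls among unchanged genes. For the co-culture effect the shares were 83.6%, 95.5% and 100%, with 10 such calls. For the effect of vector cells they were 76.1%, 97% and 100%, with 11 such calls, and for the difference of effects 52.2%, 92.5% and 100%, with 13. In a simulation of the RAS effect with 1 list shifted by 0.5 on the log2 scale, camera called that list and 0 of the other 24. The simulated genes varied independently of each other. In the data the estimated correlation of the shifted list, the unfolded protein response genes, was 0.575. The simulation therefore cannot show how camera behaves for correlated lists.

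Alternatives covered another normalization (quantile, median centring), removal of the 30% of genes with the lowest mean signal, a trended and robust prior, array weights, only the compared groups in the fit, the mean of a gene's rows, every row of the table, the replicate number as a block, stricter thresholds, an ordinary test without the shared prior, parental cells alone as the control of the co-culture, and leaving out each array in turn. A direct comparison of RAS cells with co-cultured cells, a term for the replicate-1 arrays and the other 8 arrays alone were added after the data had been seen. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.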

Results

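Expression profiles were compared between human IMR90 fibroblasts that carry oncogenic RAS and IMR90 fibroblasts that only share medium with such cells. The RAS protein was fused to an estrogen receptor part (ER:RAS), a design that is switched on by 4-hydroxytamoxifen, and cells in which it has been active for days enter the growth arrest known as oncogene-induced senescence. Parental cells were grown alone, in an insert co-culture with vector cells, or in an insert co-culture with ER:RAS cells (RAS cells below), and RAS cells were grown alone. Each of these 4 groups had 3 arrays. Over all rows of the table, arrays of 1 group correlated at 0.993 to 0.995, whereas RAS cells and parental cells grown alone correlated at 0.960 to 0.971. The first principal component, with 69.09% of the variance, placed RAS cells and parental cells co-cultured with them on one side and both control groups on the other. The second, with 13.88%, separated RAS cells from parental cells co-cultured with them. It also placed every array of cells grown alone (3.22 to 22.64) above every co-culture array (-23.61 to -3.23). For every tested gene the mean of the 4 replicate-1 arrays equalled the mean of the other 8 arrays to within 0.0001. A fit with a term for the replicate-1 arrays, and a fit of the other 8 arrays alone, were both chosen after the data had been seen. Their values stand beside the counts of all changed genes. They also stand beside a list where they change a call or move a count of at least 4 by over 1.5 times. Single genes were compared in this way only for the largest changes and the fixed set, where a changed call is given. For other genes named from a list, no such value was compared.

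**Figure D1:**
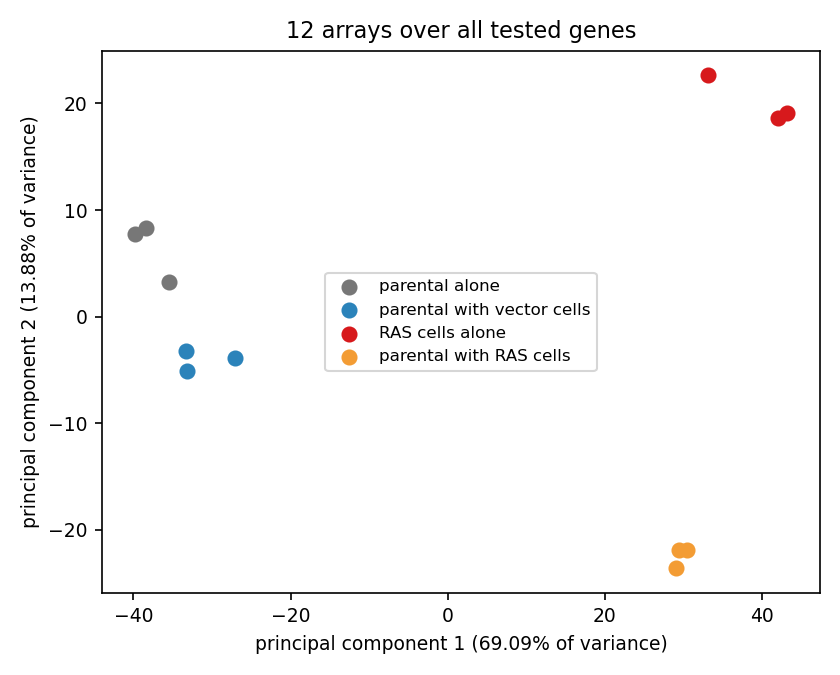
Principal component scores (arbitrary units) of the 12 arrays over the 18417 tested genes, one point per array, coloured by group. On component 1 the 6 arrays of the control groups lie between -39.79 and -27.02 and the other 6 between 29.04 and 43.19.

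The first comparison asked what RAS changed in the cells that carry it. HRAS itself (transcript cluster 7945436) rose 16.0-fold in RAS cells over parental cells (log2 change 4.00 ± 0.10 SE, n = 3 per group, adjusted p = 5.5e-12), to a log2 signal of 9.44 ± 0.18 (SD, n = 3). ESR1, which encodes an estrogen receptor, had a log2 signal of 2.77 ± 0.12 (SD, n = 3) in RAS cells and a change of 0.05 ± 0.07 (adjusted p = 0.671). The labels do not say which receptor sequence the fusion contains. The largest rises were in secreted and inflammatory genes: the matrix-degrading proteases MMP3 (233-fold) and MMP1 (159-fold), the prostaglandin synthase PTGS2 (157-fold), the neutrophil chemokines CXCL8 (157-fold) and CXCL1 (99.6-fold), the cytokine IL1B (134-fold), the chemokine CCL20 (114-fold) and the protease inhibitor TFPI2 (104-fold), with SEs of 0.127 to 0.244 on the log2 scale. The largest falls were in ADH1B, an alcohol dehydrogenase (53.8-fold lower), FMO2, a flavin monooxygenase (41.0-fold), SHISA3 (35.2-fold), the fibril-associated collagen COL14A1 (22.0-fold), the matrix protein SVEP1 (20.4-fold), the tight junction gene CLDN11 (20.1-fold), TMEM176A (19.3-fold) and the imprinted gene MEST (19.2-fold), with SEs of 0.120 to 0.295. Of 18417 genes, 3355 rose and 2821 fell, and 1127 of the changes were at least 2-fold. Rises were not the majority under every setting: 2924 genes rose and 3198 fell under quantile normalization, 3694 and 2407 under median centring, and 3924 and 4100 rows with every row of the table. With a term for the replicate-1 arrays 5715 genes were called, and the other 8 arrays alone called 5106. The 3 arrays of one group lay wholly above or below those of the other for 43.2% of genes, against 10% by chance. RAS cells were compared with parental cells, so anything the vector itself did is part of this effect. Vector cells grown alone were not analysed here.

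Secreted inflammatory genes and proteases rose in RAS cells. Of 28 secreted cytokines and chemokines, 18 rose and 1 fell (camera adjusted p = 8.66e-12; adjusted p = 0.0821 with an estimated correlation), among them IL1A (94.7-fold), IL6 (36.8-fold) and CCL2 (4.16-fold). Of 29 inflammasome and IL-1 signalling genes, 11 rose and 1 fell (adjusted p = 0.000797; 0.0821 as adjusted p with an estimated correlation), including the IL-1 receptor kinase IRAK2 (16.1-fold) and the NF-kappaB inhibitor TNFAIP3 (13.3-fold). Of 23 secreted proteases and their inhibitors, 16 rose and 3 fell (adjusted p = 3.66e-07; adjusted p = 0.00468 with an estimated correlation), including MMP10 (12.4-fold) and the urokinase receptor PLAUR (7.39-fold). Of 24 growth factors and IGF-binding proteins, 10 rose and 5 fell (adjusted p = 0.00472; adjusted p = 0.128 with an estimated correlation), led by the EGF receptor ligands EREG (48.6-fold) and HBEGF (19.7-fold) and by STC1 (42.9-fold). VEGFA rose 6.76-fold. The list of TGF-beta family ligands also holds binding proteins and inhibitors of such ligands. Of its 21 measured members, 8 rose, among them BMP2 (19.2-fold), the activin subunit INHBA (log2 change 3.91) and GDF15 (12.6-fold). Another 6 fell, among them BMP4 (4.48-fold lower), with no shift of the list (camera adjusted p = 0.399). TGFB1 rose 1.84-fold. Of 29 TGF-beta target genes, 12 rose and 12 fell (adjusted p = 0.895), and the median and the mean of their log2 changes were -0.19 and -0.03 although the test pointed up. IGFBP7 rose 1.61-fold (adjusted p = 0.0112), a call that was lost without parental replicate 1 (log2 change 0.55, adjusted p = 0.054) or RAS replicate 3 (0.57, adjusted p = 0.0529). With p-values adjusted over the list alone, 20 cytokines rose; the other lists of this paragraph kept their counts except the TGF-beta targets, of which 14 fell adjusted over the list alone.

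Over all 12 arrays, cell cycle genes were lower and cell cycle inhibitors higher in RAS cells. Parental cells were kept in 0.5% serum as well, and cells in higher serum were not compared here. The inhibitors CDKN2B (3.96-fold), CDKN1A (2.48-fold) and CDKN2A (1.44-fold) rose, with adjusted p = 1.7e-06, 0.000237 and 0.00089. Of 27 cell cycle inhibitors and p53 targets, 10 rose and 4 fell (camera adjusted p = 0.048; adjusted p = 0.375 with an estimated correlation and 0.0503, no longer called, with the replicate number as a block), including the kinase PLK3 (4.89-fold) and the death receptor TNFRSF10B (2.99-fold). Of 31 mitotic genes, 17 fell and 2 rose (adjusted p = 0.000829; adjusted p = 0.404 with an estimated correlation). ANLN was 1.99-fold and KIF11 1.79-fold lower, while the kinase AURKA was 1.84-fold higher. Of 34 DNA replication genes, 13 fell and 2 rose (adjusted p = 0.011; adjusted p = 0.325 with an estimated correlation), including the helicase subunit MCM6 (1.93-fold lower). Of 20 replication-dependent histone genes, 10 fell and 0 rose (adjusted p = 0.000852; adjusted p = 0.222 with an estimated correlation), led by H4C3 (2.57-fold lower). When adjusted over the list alone, 18 mitotic genes fell and the other counts stood. The proliferation marker MKI67 was 1.67-fold lower (adjusted p = 0.0243) and cyclin A2, CCNA2, 1.53-fold lower (adjusted p = 0.0146). Both calls were lost without parental replicate 1 (adjusted p = 0.107 and 0.0697) and without RAS replicate 1 (adjusted p = 0.103 and 0.0685). In the 8 arrays with numbers 2 and 3 the log2 changes of MKI67 and CCNA2 were -0.26 and -0.30 (adjusted p = 0.222 and 0.117). In those arrays 3 mitotic genes fell and 3 rose, 6 replication genes fell and 4 rose, and 10 inhibitors or p53 targets rose and 6 fell. None of these 3 lists was shifted there (adjusted p = 0.0614, 0.221 and 0.103). LMNB1, a lamin gene that falls in many senescent cells, had a log2 signal of 2.83 ± 0.01 (SD, n = 3) in RAS cells and a change of -0.10 ± 0.09 (adjusted p = 0.447); its signal was below the array medians in all 4 groups. Of 20 nuclear lamina and chromatin genes, 3 rose and 4 fell (adjusted p = 0.895; 4 rose and 4 fell adjusted over the list alone, 5 rose and 2 fell in the 8 arrays), with HMGA1 3.49-fold higher and HMGB2 2.61-fold lower.

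Matrix, contractile and identity genes of fibroblasts fell in RAS cells, and several stress and metabolic groups rose. The matrix and identity lists share members, among them COL1A1 and DCN, so their falls are not independent. Of 33 matrix genes, 24 fell and 5 rose (camera adjusted p = 3.29e-10; adjusted p = 0.0821 with an estimated correlation), led by decorin, DCN (10.4-fold lower), COL15A1 (7.05-fold) and FBLN1 (6.70-fold). Of 16 contractile genes, 11 fell and 0 rose (adjusted p = 1.94e-08; adjusted p = 0.0683 with an estimated correlation), including TAGLN (6.14-fold lower) and the smooth muscle actin ACTG2 (5.31-fold). Of 18 fibroblast identity markers, 13 fell and 1 rose (adjusted p = 6.31e-07; adjusted p = 0.0372 with an estimated correlation), including TCF21 (4.57-fold lower) and COL1A1 (4.21-fold). Of 30 RAS-MAPK output and feedback genes, 23 rose and 1 fell (adjusted p = 3.69e-12; adjusted p = 0.00468 with an estimated correlation), among them LIF (22.3-fold) and the ERK phosphatase DUSP6 (7.92-fold). Hypoxia and glycolysis genes rose for 22 of 27 members and fell for 1 (adjusted p = 5.86e-11; adjusted p = 0.0872 with an estimated correlation), with CA12 10.2-fold and hexokinase HK2 6.65-fold higher. Cholesterol genes rose for 13 of 18 (adjusted p = 2.17e-07; adjusted p = 0.185 with an estimated correlation; INSIG1, 6.37-fold). Unfolded protein response genes rose for 18 of 25 and fell for 1 (adjusted p = 2.95e-06; adjusted p = 0.325 with an estimated correlation; DNAJB9, 3.62-fold). NRF2 and oxidative stress genes rose for 15 of 24 and fell for 1 (adjusted p = 4.68e-06; adjusted p = 0.0821 with an estimated correlation; the metallothionein MT1X, 4.51-fold). Of 23 lysosomal genes, 9 rose and 2 fell (adjusted p = 0.0473; adjusted p = 0.404 with an estimated correlation and 0.0503, no longer called, with the replicate number as a block), led by the cholesterol transporter NPC1 (6.83-fold). Their median log2 change of 0.12 turned to -0.01 under quantile normalization, and in the 8 arrays with numbers 2 and 3 it was 0.04, with 7 up, 4 down and no shift (adjusted p = 0.464). Interferon genes were not shifted as a list (7 of 29 rose and 4 fell, adjusted p = 0.101), although CXCL10 rose 28.3-fold. Adjusted over the list alone, 25 matrix genes fell, 24 RAS-MAPK genes rose and 2 fell, 16 NRF2 genes and 19 unfolded protein response genes rose, and the other counts stood. Some markers of other cell types were called, in a comparison that called 33.5% of all tested genes. In RAS cells 2 of 13 epithelial, 2 of 12 endothelial and 2 of 11 blood cell markers rose and 1 of each list fell. CD68, a lysosomal glycoprotein used as a macrophage marker, was 3.49-fold higher and TEK 2.96-fold lower. None of these 3 lists was shifted (adjusted p = 0.948, 0.738 and 0.895). Of 12 reference genes, 5 rose (3 under quantile normalization) and 1 fell (adjusted p = 0.0879), with a median log2 change of 0.12, which was 0.07 under quantile normalization and 0.16 under median centring. In the 8 arrays with numbers 2 and 3 the median of the reference genes was 0.25.

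The second comparison asked what RAS cells changed in parental cells behind a porous insert, with parental cells next to vector cells as the control. HRAS did not pass the test in these cells (log2 change 0.10 ± 0.10, n = 3 per group, adjusted p = 0.561), and ESR1 did not either (0.04 ± 0.07, adjusted p = 0.776). The largest rises were again MMP3 (264-fold), CXCL8 (144-fold) and IL1B (82.0-fold), followed by the decoy receptor IL13RA2 (66.9-fold), PTGS2 (59.4-fold), CCL20 (56.9-fold), MMP10 (47.1-fold) and IL6 (44.8-fold), with SEs of 0.178 to 0.426 on the log2 scale. The largest falls were ADH1B (60.8-fold lower), the laminin subunit LAMA4 (43.2-fold), SHISA3 (42.5-fold), COL14A1 (28.8-fold), the microfibril gene MFAP4 (20.7-fold), GASK1B (16.8-fold), SVEP1 (16.7-fold) and ACTG2 (13.9-fold), with SEs of 0.117 to 0.297. In all, 1964 genes rose and 2279 fell, 23.0% of those tested, and 751 changes were at least 2-fold. The fit with a term for the replicate-1 arrays called 3777 genes and the other 8 arrays alone 3405. The groups did not overlap for 37.6% of genes, against 10% by chance.

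**Figure D2:**
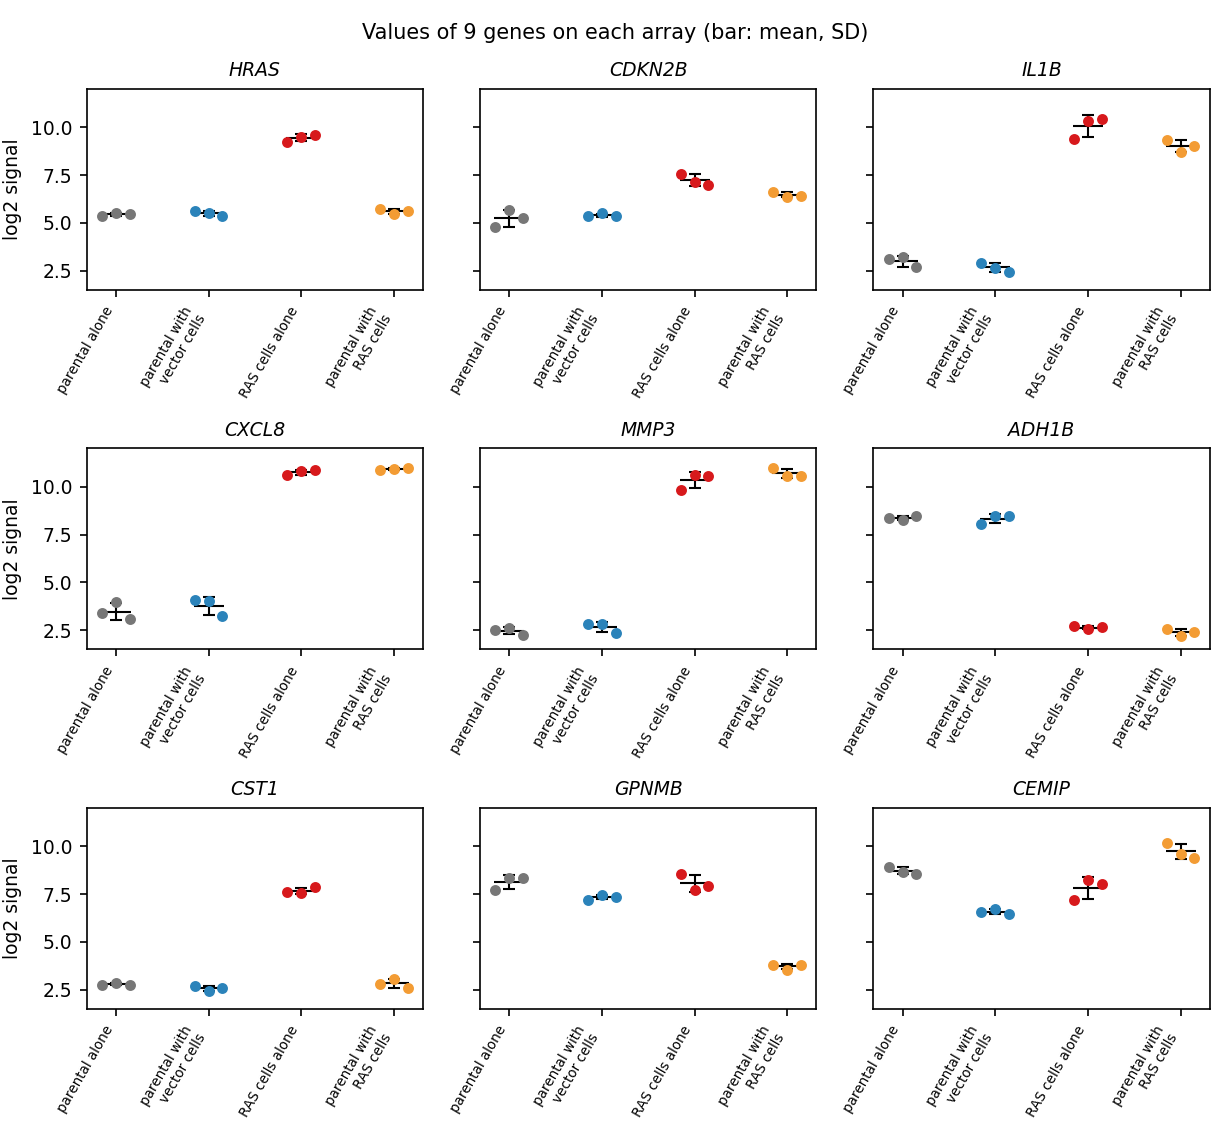
Log2 signals of 9 genes on each of the 12 arrays (points), with the mean and SD of the 3 arrays of each group (bars). HRAS is high in RAS cells alone, at 9.44, while IL1B, CXCL8 and MMP3 are high and ADH1B is low both in RAS cells and in parental cells co-cultured with them; CST1, GPNMB and CEMIP differ between those 2 groups.

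The same kinds of secreted genes rose in co-cultured cells. Of the 28 cytokines and chemokines, 18 rose and 1 fell (camera adjusted p = 8.1e-14; adjusted p = 0.0728 with an estimated correlation), with IL1A 37.5-fold and CCL2 2.69-fold higher. Of the 29 IL-1 signalling genes, 11 rose and 1 fell (adjusted p = 8.87e-05; adjusted p = 0.0632 with an estimated correlation), with IRAK2 8.47-fold higher. Of the 23 proteases and inhibitors, 11 rose and 5 fell (adjusted p = 0.00334; adjusted p = 0.0541 with an estimated correlation), with MMP1 39.4-fold higher. Of the 24 growth factors, 10 rose and 6 fell (adjusted p = 0.00269; adjusted p = 0.111 with an estimated correlation), including EREG (13.3-fold), STC1 (8.26-fold) and VEGFA (4.78-fold). In the list of TGF-beta family ligands and their binding proteins, 6 of 21 members rose and 5 fell (camera adjusted p = 0.293). BMP2 was 22.6-fold, INHBA 4.26-fold and the activin-binding protein FST 4.23-fold higher. TGF-beta targets rose for 13 of 29 and fell for 12 (adjusted p = 0.5), with SKIL 2.83-fold higher and ACTA2 3.62-fold lower. TGFB1 rose 2.09-fold and IGFBP7 2.66-fold. RAS-MAPK output genes rose for 21 of 30 and fell for 2 (adjusted p = 2.12e-11; adjusted p = 0.0118 with an estimated correlation), including LIF (10.7-fold) and the feedback inhibitor SPRY4 (5.30-fold). Counts adjusted over the list alone differed for some lists: 12 proteases rose and 6 fell, 11 growth factors, 7 members of the TGF-beta ligand list and 22 RAS-MAPK genes rose, 13 TGF-beta targets fell, and the other counts stood.

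Matrix and contractile genes fell in co-cultured cells too. Matrix genes fell for 22 of 33 and rose for 5 (camera adjusted p = 6.92e-10; adjusted p = 0.0778 with an estimated correlation), including FBLN1 (8.32-fold lower) and DCN (6.07-fold). Contractile genes fell for 13 of 16 and rose for 0 (adjusted p = 4.91e-11; adjusted p = 0.048 with an estimated correlation), and fibroblast identity markers fell for 12 of 18 and rose for 3, or 1 in the 8 arrays (adjusted p = 2.52e-06; adjusted p = 0.048 with an estimated correlation), with THY1 6.22-fold lower. Hypoxia and glycolysis genes rose for 23 of 27 and fell for 1 (adjusted p = 1.68e-12; adjusted p = 0.0778 with an estimated correlation), with CA12 8.37-fold higher. Unfolded protein response genes rose for 20 of 25 and fell for 0 (adjusted p = 2.56e-10; adjusted p = 0.213 with an estimated correlation), with DNAJB9 3.42-fold and the chaperone regulator HYOU1 2.54-fold higher. Cholesterol genes rose for 7 of 18 and fell for 1 (adjusted p = 0.00815; adjusted p = 0.553 with an estimated correlation). Lysosomal genes fell for 11 of 23 and rose for 1 (adjusted p = 0.000285; adjusted p = 0.212 with an estimated correlation). The ceramidase ASAH1 was 1.71-fold and the hexosaminidase HEXA 1.61-fold lower, and NPC1 was 2.85-fold higher. NRF2 genes rose for 6 of 24 and fell for 7 (adjusted p = 0.865), with MT1X 3.30-fold higher and AKR1C2 2.20-fold lower. Interferon genes rose for 3 of 29 and fell for 5 (adjusted p = 0.603), with CXCL10 higher by 4.32 on the log2 scale and IFIT1 3.00-fold lower. Counted after p-values were adjusted over the list alone, 23 matrix genes, 13 identity markers, 15 lysosomal genes, 6 interferon genes and 2 hypoxia genes fell. In the same count, 6 matrix, 24 hypoxia, 22 unfolded protein response, 10 cholesterol, 2 lysosomal and 4 interferon genes rose. The other counts of these lists stood. Of markers of other cell types, CD68 (2.36-fold higher), ELF3 (1.38-fold higher) and TEK (2.87-fold lower) were the only ones called among 36 in these lists, none of which was shifted (adjusted p = 0.497 for epithelial, 0.799 for endothelial and 0.497 for blood cell markers). Of the 12 reference genes, 3 rose and 2 fell (camera adjusted p = 0.441), and 5 rose and 3 fell adjusted over the list alone. Their median was 0.16, with 0.14 under quantile normalization, 0.17 under median centring and 0.10 in the 8 arrays.

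Of the cell cycle inhibitors, CDKN2B alone among CDKN1A, CDKN2A and CDKN2B passed the test in co-cultured cells. CDKN2B rose 2.11-fold (adjusted p = 0.0007), while CDKN1A (log2 change 0.38 ± 0.21, adjusted p = 0.242) and CDKN2A (-0.09 ± 0.10, adjusted p = 0.623) did not pass. CDKN1A passed in the 8 arrays with numbers 2 and 3 (0.58, adjusted p = 0.0277). Of the 27 inhibitors and p53 targets, 6 rose and 8 fell (camera adjusted p = 0.799), with GDF15 4.14-fold higher and TP53INP1 2.43-fold lower. Mitotic genes fell for 13 of 31 and rose for 1 (adjusted p = 5.09e-05; adjusted p = 0.351 with an estimated correlation), and replication genes fell for 10 of 34 and rose for 1 (adjusted p = 0.00183; adjusted p = 0.228 with an estimated correlation). CCNA2 was 1.82-fold lower (adjusted p = 0.00237), RRM1 1.72-fold lower and TOP2A 1.91-fold lower. MKI67 (log2 change -0.60 ± 0.23, adjusted p = 0.0848) and LMNB1 (-0.11 ± 0.09, adjusted p = 0.444) did not pass. Histone genes fell for 3 of 20 and rose for 1 (adjusted p = 0.311), and lamina and chromatin genes fell for 4 of 20 and rose for 1 (adjusted p = 0.705), with HMGA1 3.55-fold higher. Only 1 histone gene fell and 3 rose in the 8 arrays, where 1 lamina or chromatin gene fell. When p-values were adjusted over the list alone, 16 mitotic and 13 replication genes and 9 inhibitors or p53 targets fell, 2 mitotic genes rose, and the other counts stood.

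The effects of RAS and of co-culture with RAS cells were compared across genes. Over the 18417 genes, which are not independent replicates, the log2 changes correlated at a Pearson r of 0.81 (leaving out 1 array at a time gave 0.79 to 0.82) and a Spearman rho of 0.59, with a slope of 0.667 for the co-culture effect on the RAS effect. Genes that rose in both numbered 1496, against 358 expected for independent lists of these sizes, and 1548 fell in both, against 349. They made up 76.2% of the genes that rose and 67.9% of those that fell in co-culture. Only 87 genes rose with RAS and fell in co-culture, against 415 expected, and 16 did the reverse, against 301. Among the 3044 genes called in the same direction in both, the median ratio of the co-culture effect to the RAS effect was 0.83. That ratio leaves out genes with a co-culture effect too weak to be called. Of the 6176 genes called for RAS, 3147 were called in co-culture in either direction.

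**Figure D3:**
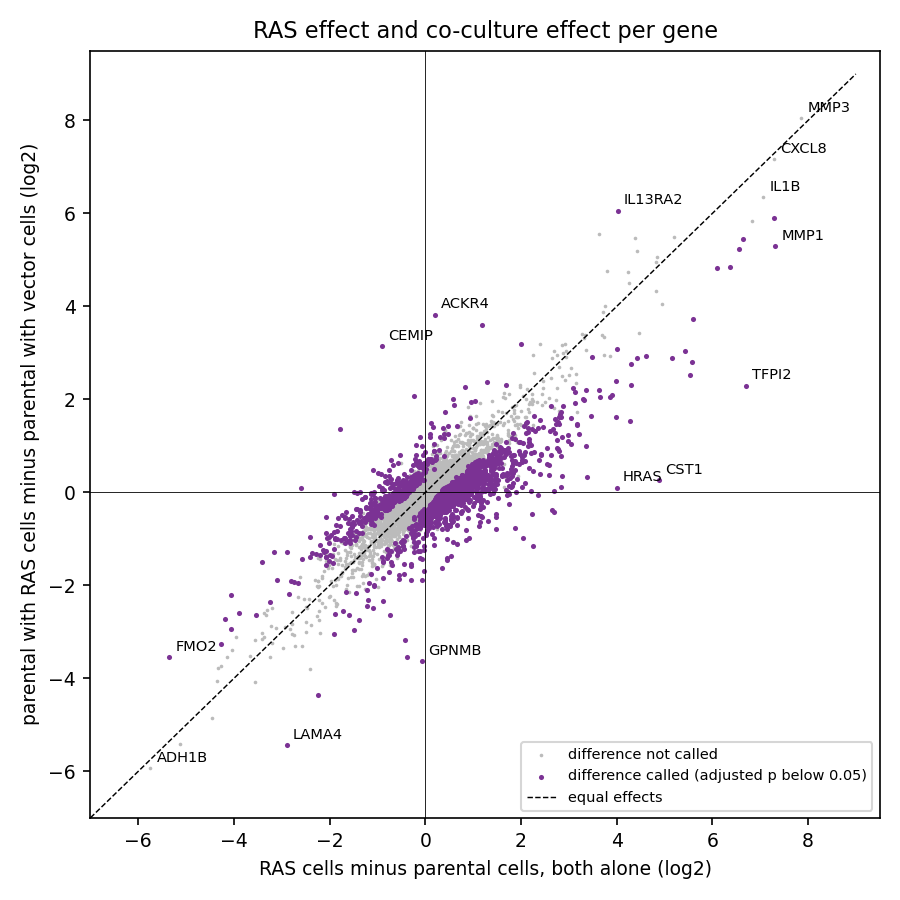
Log2 change of each tested gene in RAS cells (horizontal axis) and in parental cells co-cultured with RAS cells (vertical axis), with equal effects on the dashed line; purple marks the genes whose effects differed. The points follow a slope of 0.667, MMP3 and ADH1B lie near the dashed line, and HRAS, CST1 and TFPI2 lie below it.

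The test of the difference between both effects called 1656 genes, of which 1173 had the higher value for the RAS effect and 483 for the co-culture effect. Under quantile normalization this split became 853 against 685. With a term for the replicate-1 arrays 1271 genes were called, and the other 8 arrays alone called 1159. CST1, a salivary-type cystatin, was the largest: it rose with RAS to a log2 signal of 7.68 ± 0.16 (SD, n = 3) and stayed at 2.84 ± 0.24 in co-cultured cells, a difference of effects of 24.8-fold (SE 0.16 on the log2 scale, adjusted p = 4.48e-09). It was followed by TFPI2 (21.1-fold), HRAS (14.9-fold), GPNMB (11.7-fold) and MEDAG (10.7-fold). TFPI2 had a log2 signal of 10.46 ± 0.24 (SD, n = 3) in co-cultured cells and 9.98 ± 0.20 in RAS cells, while its controls were at 8.17 ± 0.23 next to vector cells and 3.28 ± 0.18 alone. GPNMB, a transmembrane glycoprotein, was 8.06 ± 0.44 in RAS cells, 8.13 ± 0.37 in parental cells alone, 7.35 ± 0.13 next to vector cells and 3.72 ± 0.15 next to RAS cells. In the other direction lay the hyaluronidase-linked gene CEMIP (-4.06 ± 0.33 on the log2 scale), the chemokine scavenger ACKR4 (-3.62 ± 0.22), ABI3BP (-3.15 ± 0.23), the adhesion molecule VCAM1 (-2.70 ± 0.46) and RASGRP3 (-2.42 ± 0.35), with adjusted p = 8.72e-06, 5.74e-07, 2.6e-06, 0.00241 and 0.000751. A second row annotated to ACKR4 gave a smaller difference of the same sign (-0.57, adjusted p = 0.00588), and the changes in co-culture were 3.82 and 0.49 for the 2 rows. Whether the brighter row measures ACKR4 or a related copy was not settled. The controls of CEMIP differed: its arrays lay at 8.6 to 8.9 in parental cells alone and 6.5 to 6.7 next to vector cells. They lay at 7.2 to 8.2 in RAS cells and 9.4 to 10.2 next to RAS cells. Its difference of effects therefore holds a gap between the controls as well. Among the fixed genes, the difference was upward for MMP1 (4.02-fold), INHBA (3.52-fold), CCL2 (1.55-fold) and CDKN2A (1.53-fold). CCL2 was at 10.52 in RAS cells and 10.68 in co-cultured cells, and its controls were at 8.47 alone and 9.25 next to vector cells. For MMP1 these values were 10.81, 10.41, 3.50 and 5.11. CDKN2A was no longer called under quantile normalization (0.48, adjusted p = 0.0717) or in the 8 arrays with numbers 2 and 3 (0.50, adjusted p = 0.106). IL1A (2.52-fold, adjusted p = 0.0414) and CDKN2B (1.88-fold, adjusted p = 0.0481) also passed, and both calls were lost under quantile normalization (adjusted p = 0.0576 and 0.113) and without most single arrays. Both were also lost with the replicate number as a block (adjusted p = 0.0786 and 0.0784) and with a term for the replicate-1 arrays (0.0573 and 0.0683). The trended robust prior ended the call of IL1A (adjusted p = 0.0754). IL1A passed in the 8 arrays with numbers 2 and 3, and CDKN2B did not (0.62, adjusted p = 0.101). For IL1A the adjusted p was 0.0717 and 0.0964 without parental replicates 2 and 3, 0.0901 and 0.0892 without RAS replicates 2 and 3. It was 0.0914, 0.0522 and 0.0688 without vector replicates 1 to 3, and 0.088 and 0.0915 without co-culture replicates 2 and 3. For CDKN2B it was 0.0854 and 0.0867 without parental replicates 1 and 3, 0.0923 and 0.0603 without RAS replicates 1 and 2. It was 0.0706, 0.107 and 0.0809 without vector replicates 1 to 3, and 0.0506, 0.105 and 0.0929 without co-culture replicates 1 to 3. For CXCL8, MMP3, IL6, IL1B, VEGFA, TGFB1, CDKN1A, MKI67, CCNA2, LMNB1, ESR1, CCL20 and IGFBP7 the difference did not pass (adjusted p from 0.0738 to 0.97). CCL20 and IL1B passed without RAS replicate 1 (adjusted p = 0.00177 and 0.0233), as did CDKN1A without parental replicate 2 (0.0149) and IGFBP7 without vector replicate 1 (0.0356). VEGFA (1.00, adjusted p = 0.00257), CCL20 (1.53, adjusted p = 0.000481), IL1B (1.12, adjusted p = 0.0197) and IGFBP7 (-0.78, adjusted p = 0.018) passed in the 8 arrays. CXCL8, PTGS2 and MMP1 lay between 10.41 and 10.93 on the log2 scale in both RAS arms, near the highest value of the table, 11.86.

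By list, NRF2, lysosomal and cholesterol genes were higher for the RAS effect than for the co-culture effect. The difference was called upward for 10 of 24 NRF2 genes and downward for 0 (camera adjusted p = 2.57e-09; adjusted p = 0.0661 with an estimated correlation), led by AKR1C1 (4.79-fold) and SRXN1 (2.67-fold). It was called upward for 12 of 23 lysosomal genes and downward for 0 (adjusted p = 3.2e-10; adjusted p = 0.0661 with an estimated correlation), led by NPC1 (2.40-fold) and the sialidase NEU1 (2.19-fold). It was called upward for 8 of 18 cholesterol genes and downward for 0 (adjusted p = 1.54e-06; adjusted p = 0.294 with an estimated correlation). The 8 arrays with numbers 2 and 3 gave 6 cholesterol genes upward and 2 downward, with a median of 0.326 in place of 0.625. Proteases (8 of 23 upward, 0 downward, adjusted p = 6.53e-05; adjusted p = 0.0314 with an estimated correlation), p53 targets and inhibitors (10 upward, 1 downward, adjusted p = 8.17e-05; adjusted p = 0.14 with an estimated correlation) and RAS-MAPK output genes (9 upward, 1 downward, adjusted p = 0.000375; adjusted p = 0.0661 with an estimated correlation) were also higher for RAS, with the urokinase PLAU at 3.16-fold and DUSP5 at 3.84-fold. Of the p53 targets and inhibitors, 4 were called upward under quantile normalization and 5 in the 8 arrays with numbers 2 and 3. Interferon genes (2 upward of 29, adjusted p = 0.00815; adjusted p = 0.0661 with an estimated correlation) and hypoxia genes (3 upward, 1 downward, adjusted p = 0.0367; adjusted p = 0.606 with an estimated correlation) were shifted upward with few members called. Of the hypoxia genes, 1 was called upward under quantile normalization and 7 in the 8 arrays. Histone genes (4 downward, 1 upward, adjusted p = 0.00201; adjusted p = 0.328 with an estimated correlation), identity markers (2 downward, 1 upward, adjusted p = 0.0116; adjusted p = 0.226 with an estimated correlation) and matrix genes (7 downward, 2 upward, adjusted p = 0.0259; adjusted p = 0.606 with an estimated correlation) were shifted downward, with COL3A1 at 2.91-fold and H4C3 at 2.59-fold lower. Downward calls of identity markers numbered 6 under quantile normalization and 4 in the 8 arrays. Upward calls of matrix genes numbered 4 under median centring, and 0 under quantile normalization and with a term for the replicate-1 arrays. Cytokines were not shifted (3 upward, 1 downward of 28, adjusted p = 0.128), nor were mitotic (adjusted p = 0.931), replication (adjusted p = 0.931) or unfolded protein response genes (adjusted p = 0.364). Cytokines were shifted upward in the 8 arrays with numbers 2 and 3 (9 upward, 1 downward, adjusted p = 9.43e-05), as were IL-1 signalling genes (adjusted p = 0.0306), growth factors (adjusted p = 0.002) and reference genes (adjusted p = 0.0149). Unfolded protein response genes were shifted downward there (adjusted p = 0.00885). The corresponding adjusted p-values over all 12 arrays were 0.253 for IL-1 signalling genes, 0.0568 for growth factors and 0.128 for reference genes. The counts adjusted over the list alone were, upward and downward, 17 and 0 for NRF2, 16 and 1 for lysosomal, 9 and 0 for cholesterol, 10 and 1 for protease and 14 and 2 for p53 target genes. They were 11 and 2 for RAS-MAPK, 3 and 0 for interferon, 5 and 1 for hypoxia, 1 and 5 for histone, 1 and 8 for identity and 8 and 11 for matrix genes.

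**Figure D4:**
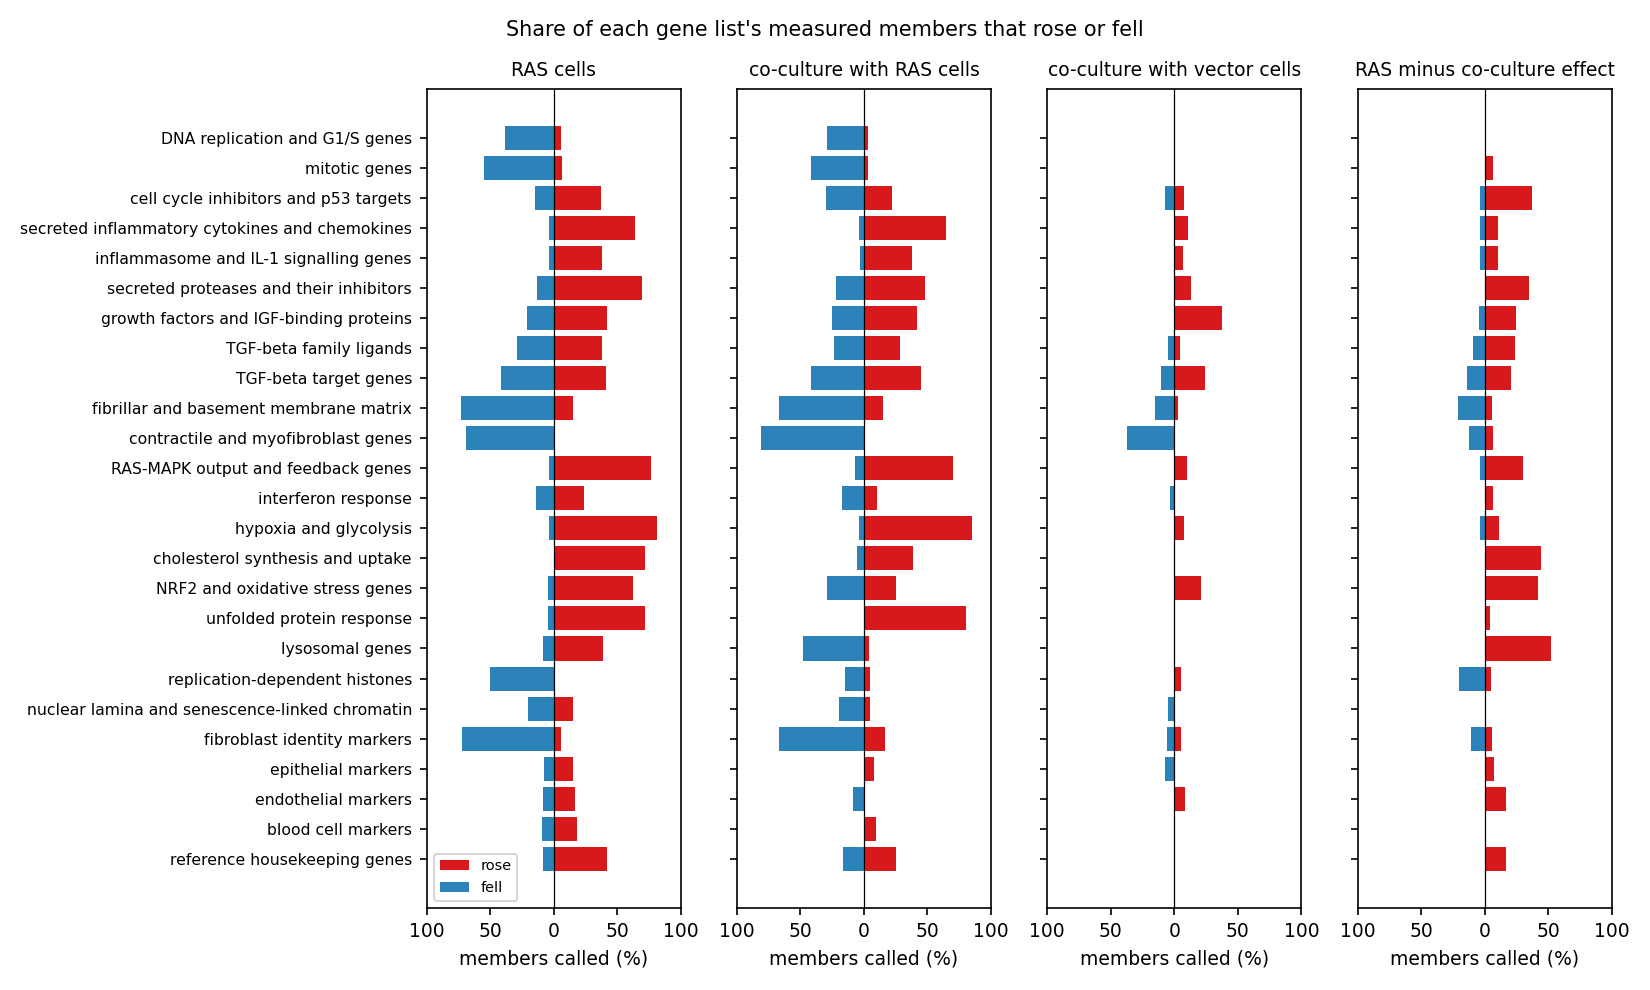
Percentage of the measured members of each of 25 gene lists that rose (red, to the right) or fell (blue, to the left) in the 3 comparisons and in the difference of effects. Cytokine, hypoxia and RAS-MAPK lists rise and matrix and contractile lists fall with RAS and in co-culture with RAS cells, while lysosomal genes rise for 9 of 23 members with RAS and fall for 11 in co-culture.

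The third comparison asked what an insert with vector cells changed in parental cells. It called 602 genes, of which 390 rose and 212 fell, and 67 changed at least 2-fold. With a term for the replicate-1 arrays it called 384, with the replicate number as a block 346, and in the other 8 arrays alone 584. The largest rises were TFPI2 (29.5-fold), the endothelin receptor EDNRB (9.38-fold), the nuclear receptor NR4A2 (8.01-fold), PDK4, a kinase that restrains pyruvate oxidation (8.01-fold), and the phosphodiesterase PDE7B (7.29-fold). The largest falls were CEMIP (4.38-fold lower), FMO2 (3.37-fold), the chloride channel ANO1 (2.97-fold), DEPP1 (2.67-fold) and the smooth muscle actin ACTA2 (2.43-fold). DEPP1 was not called without parental replicate 2 (adjusted p = 0.0725) or 3 (0.0756) or vector replicate 1 (0.0561) or 3 (0.0772). Of the fixed genes, MMP1 (3.05-fold) and CCL2 (1.73-fold) rose, and the other 18 did not pass; VEGFA, at 1.52-fold (adjusted p = 0.0523), passed without parental replicate 1 (adjusted p = 0.0157) or vector replicate 1 (0.0224). It also passed under quantile normalization (adjusted p = 0.0493), median centring (0.0385) and the trended robust prior (0.0416). VEGFA rose (0.91, adjusted p = 0.000726), and IL6 (-0.76, adjusted p = 0.0192) and IGFBP7 (-0.64, adjusted p = 0.0116) fell, in the 8 arrays with numbers 2 and 3. Growth factors rose for 9 of 24 and fell for 0 (camera adjusted p = 2.36e-08; adjusted p = 0.0404 with an estimated correlation), with STC1 3.95-fold and EREG 2.93-fold higher. Contractile genes fell for 6 of 16 (adjusted p = 2.9e-06; adjusted p = 0.129 with an estimated correlation), including TAGLN (2.36-fold lower), and NRF2 genes rose for 5 of 24 (adjusted p = 2.9e-06; adjusted p = 0.129 with an estimated correlation), including NQO1 (1.98-fold). TGF-beta targets rose for 7 of 29 and fell for 3 (adjusted p = 0.0367; adjusted p = 0.129 with an estimated correlation), with ID3 2.77-fold higher. Among these lists, adjusted over the list alone, 12 growth factors, 7 NRF2 genes, 11 TGF-beta targets and 1 contractile gene rose and 9 contractile genes and 6 TGF-beta targets fell. With a term for the replicate-1 arrays 5 growth factors and 3 NRF2 genes rose. Cytokines rose for 3 of 28 (adjusted p = 0.0413; adjusted p = 0.611 with an estimated correlation), and IL1B, IL6 and CXCL8 were not among them. Hypoxia genes (2 of 27 rose, adjusted p = 0.000382; adjusted p = 0.379 with an estimated correlation) and histone genes (1 of 20 rose, adjusted p = 0.00138; adjusted p = 0.291 with an estimated correlation) were shifted upward; 5 hypoxia genes rose in the 8 arrays, and 3 histone genes under median centring. Of 6 further lists that camera called, mitotic, IL-1 signalling, protease, RAS-MAPK and reference genes were shifted upward and epithelial markers downward, with at most 3 members called in any of them, or 6 in the 8 arrays (adjusted p from 0.0393 to 0.0469; adjusted p from 0.129 to 0.635 with an estimated correlation). In the 8 arrays with numbers 2 and 3, TGF-beta targets, IL-1 signalling genes and epithelial markers were no longer shifted (adjusted p = 0.0546, 0.0546 and 0.129). Cholesterol genes were shifted downward there, with 5 of 18 lower (adjusted p = 8.3e-07; 0.937 over all 12 arrays), as were lysosomal genes (adjusted p = 0.00338) and p53 targets and inhibitors (adjusted p = 0.00336), and lamina and chromatin genes were shifted upward (adjusted p = 0.029). With the replicate number as a block, mitotic genes and epithelial markers were no longer shifted (adjusted p = 0.0561 for both). The number of called genes depended on single arrays: it was 276 without parental replicate 2, 348 without parental replicate 3, 362 without vector replicate 2 and 278 without vector replicate 3.

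This comparison shares arrays with both others. The effects of vector cells and of RAS, which share parental cells alone, correlated at 0.325 across genes, below the 0.499 that unchanged groups gave against those controls, while the covariance was 0.038 against a simulated 0.0064. In both, 212 genes rose and 148 fell, against 71.0 and 32.5 for independent lists. A further 66 rose with vector cells and fell with RAS, against 59.7, and 14 did the reverse, against 38.6. The effects of vector cells and of co-culture with RAS cells correlated at 0.118, against -0.502 in the simulation, with a covariance of 0.0114 against -0.0064. In both, 130 genes rose and 107 fell, against 41.6 and 26.2 for independent lists. Another 121 rose with vector cells and fell in co-culture with RAS cells, against 48.3, and 21 did the reverse, against 22.6. The 3 shared arrays cannot be split into parts of at least 2, so part of the excess with the RAS effect may come from the shared controls. The arrays next to vector cells enter the other pair with opposite signs. Part of the excess in the 121 genes called in opposite directions may therefore come from these arrays.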

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

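The tests of RNA carry-over, of the insert, of the control groups for the NRF2 and lysosomal lists, of other splits for the 3 simple comparisons and of the slope over genes lower with RAS were chosen after the results had been seen, as were the joint value of the 2 corrections and the direct gap between RAS cells and co-cultured cells. The slopes under another control, under correction for error and below the array ceiling, the scaling test and the splits of the difference were chosen before their values were known. Groups of 3 arrays were not tested for outlying samples.

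The RAS effect and the co-culture effect differed for 1656 genes by the test of the difference itself, and 103 genes were called in opposite directions. Of 100 splits of the control arrays and of the RAS arrays, drawn from 200, 2 gave as many genes, the real one included, and the highest other gave 1807. The splits with the most genes left the RAS arrays in their groups and exchanged control arrays, so this test mostly follows the gap between RAS cells and co-cultured cells. For the RAS effect, 1 of 10 splits of the 6 arrays gave 6176 genes, the real one, and the highest other gave 0; for co-culture with RAS cells 1 of 10 gave 4243 and the highest other 0; for co-culture with vector cells 1 of 10 gave 602 and the highest other 4. With 10 splits no share under 0.05 can be reached.

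The first pattern is that co-culture with RAS cells moved 3044 genes the same way as RAS itself. Carry-over of RAS cells or their RNA is argued against by HRAS: its change in co-cultured cells corresponds to 0.51% of RAS-cell RNA, with an upper 95% bound of 1.74% (1.83% with a term for the replicate-1 arrays), whereas these 3044 genes need a median share of 88.9%. An effect of any second cell population is argued against by the 6176 genes called for RAS, chosen without either co-culture: signed by direction and against parental cells alone, their median change next to vector cells was 0.178 (SE 0.04) of that next to RAS cells. This replaced a first test over the 3044 genes, with a ratio of 0.0798, whose choice already subtracts the vector co-culture. A response of parental cells to factors released by RAS cells, which the design names, may account for the pattern and stays a hypothesis, since no factor was removed or added here.

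The second pattern is that co-culture effects were smaller. Their SD across genes was 0.483 on the log2 scale, against 0.586 for the RAS effects. The slope on the RAS effects was 0.667 (SE 0.03). A slope below 1 also arises where the 2 effects differ from gene to gene, and the slopes given here do not separate this from size. With parental cells alone as the control of both, and the shared covariance removed, the slope was 0.759 (SE 0.02). A control that lies part of the way is therefore not the whole of a slope below 1. Correction for error in the RAS effect gave 0.693. The array ceiling stays open: the slope of 0.65 over the 17981 genes below 9 in every group decides nothing, since that limit removes genes by their rise, and the slope over the 2821 genes lower with RAS, which move away from the ceiling, was 0.782 (SE 0.04), within its SE of 0.8. The change of control and the correction for error together gave 0.788 (SE 0.02), also within its SE of 0.8, the bound set for each of them, so their joint part stays open, as does a weaker or later response of co-cultured cells, since neither dose nor time was varied.

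The third pattern is that NRF2 and lysosomal genes differed between the effects, with medians of 0.488 and 0.376 on the log2 scale, and another scaling of the arrays kept at least 82.1% of their joint median. Taken separately, the medians were 0.426 and 0.283 under quantile normalization and 0.516 and 0.403 under median centring. The change made by vector cells amounted to 32.4% (SE 14.1) of the NRF2 difference and to -20.4% (SE 18.1) of the lysosomal one, so a difference between the control groups may account for part of the NRF2 shift, where the distance to 50% is little more than 1 SE, and not for most of the lysosomal one. In the 8 arrays with numbers 2 and 3 these shares were 45.4% and -43.2%. These per-list shares replaced a first test, the direct gap between RAS cells and co-cultured cells, which was 86.4% (SE 18.4) of the joint difference and left the question undecided. In the lysosomal list the difference held a fall in co-cultured cells (median -0.237), while the median with RAS was 0.12. Under quantile normalization these medians were -0.236 and -0.009. A cell-intrinsic effect of RAS is 1 biological explanation the design offers, but it would not cover a fall in co-cultured cells. The RAS effect also holds anything the vector itself did. The cell-intrinsic explanation stays open. With camera adjusted p-values of 0.0661 for both lists with an estimated correlation, the shift itself stays open too.

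Other differences of effects are given as values on the log2 scale, and they include differences between the controls. A higher value for RAS can mean a larger rise or a smaller fall, and a lower value the reverse. LAMA4 and MFAP4, for example, were among the largest falls in co-culture, and GPNMB did not rise with RAS. Higher for RAS were CST1 (4.63), TFPI2 (4.40), HRAS (3.90), GPNMB (3.55), MEDAG (3.42), LAMA4 (2.53), MFAP4 (2.12), MMP1 (2.01), INHBA (1.82), PTGS2 (1.41), IL1A (1.33), CXCL1 (1.19), CDKN2B (0.91), CCL2 (0.63) and CDKN2A (0.61). Lower were TMEM176A (-1.01), FMO2 (-1.81), IL13RA2 (-2.04), RASGRP3 (-2.42), VCAM1 (-2.70), ABI3BP (-3.15), ACKR4 (-3.62, or -0.57 for a second row, and which of them measures ACKR4 was not settled) and CEMIP (-4.06). Median differences of the other lists that were shifted by camera were 0.625 for cholesterol genes, 0.473 for cell cycle inhibitors and p53 targets, 0.421 for proteases, 0.276 for RAS-MAPK output genes, 0.142 for hypoxia and glycolysis, 0.103 for interferon genes, -0.173 for matrix genes, -0.284 for histones and -0.303 for fibroblast identity markers. Some of these medians moved by more than 1.5 times. In the 8 arrays with numbers 2 and 3 they were 0.326 for cholesterol genes, 0.222 for inhibitors and p53 targets, 0.328 for hypoxia, 0.159 for interferon genes and -0.19 for identity markers. Under quantile normalization they were 0.063 for hypoxia, 0.161 for RAS-MAPK output genes and 0.159 for interferon genes.

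Signal also appeared in rows outside the tested genes. Of 13837 rows with no gene symbol or several, 2016 changed in RAS cells, 783 in co-culture with RAS cells and 169 in co-culture with vector cells, by limma over all rows of the table. Their median log2 signal was 2.73, against 3.92 for the tested genes.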

How the results depend on the processing

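For single genes, alternatives were run on 121 values, those of the largest changes and the fixed set. These alternatives were the replicate block, quantile normalization, median centring, the trended robust prior and the fits that treat the replicate-1 arrays apart. Leaving out 1 array was the last of them. The other settings, and genes named only from a list, were not compared gene by gene. No called value among the 121 changed sign: 1568 comparisons kept their side of the threshold, 41 lost and 17 gained a call. Of the list values under an estimated correlation, fry and the fits that treat the replicate-1 arrays apart, 415 kept it, 69 lost and 16 gained a call; the median of the lysosomal list in RAS cells turned from 0.12 to -0.01 under quantile normalization. The direct comparison of RAS cells with co-cultured cells, which called 3375 genes against 1656 for the difference of effects, was added after seeing the data; it subtracts no controls. A bound of 2-fold left 1127 genes for RAS, 751 for co-culture with RAS cells, 67 for vector cells and 352 for the difference of effects, by its construction. At an adjusted p below 0.01, 243 genes passed for vector cells and 752 for the difference; the ordinary test without a shared prior gave 285 and 1085. Without 1 array, counts ranged from 5440 to 5752 for RAS, 3464 to 3755 for co-culture with RAS cells, 276 to 501 for vector cells and 1284 to 1603 for the difference; the smaller sample accounts for lower counts in general, and the cause of the wide range for vector cells was not tested. The correlation of RAS and co-culture effects was 0.7634 with every row of the table, which adds dim rows, against 0.8095, and 0.7925 to 0.8179 without 1 array. The overlap of RAS and co-culture calls, 3044 genes, was 2638 to 3052 without 1 array and 2491 to 3306 under the other settings. With an estimated correlation, the lists called fell from 17 to 3 for RAS and from 14 to 3 for co-culture. They fell from 13 to 1 for vector cells and from 11 to 1 for the difference. Correlated members carry less evidence, but calls were also lost where the estimated correlation was below the preset 0.01. It was 0.002 for interferon genes (difference of effects) and 0.005 for TGF-beta targets (vector cells). Correlation among members therefore does not account for every lost call. The test fry, which does not compare a list with other genes, called 5 lists for vector cells. Scaling moved the median of all genes by less than 0.05. The dim end of the scale limits genes such as LMNB1, which lay below the array medians.

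Deviations of same-numbered arrays correlated at -0.43 to 0.13, and 0 of 12 arrays correlated best with their own number; since the replicate-1 arrays are centred on the others, this cannot show whether the numbers pair the arrays. Replicate 2 minus replicate 3, which the centring leaves as it was, correlated at -0.123 to 0.251 between groups. With the replicate number as a block, the counts were 5582, 3665, 346 and 1180 for RAS, co-culture with RAS cells, vector cells and the difference of effects. A term for the replicate-1 arrays, chosen after seeing the data, gave 5715, 3777, 384 and 1271, and the other 8 arrays alone, also chosen then, 5106, 3405, 584 and 1159; in the former p-values rise because 1 degree of freedom is returned. The fit of only the compared groups gives no separate value for the difference, which uses all 12 arrays.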

Other observations

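Families of genes sharing a symbol were tested after the data had been seen. In RAS cells, 38 of 55 genes with symbols of large-subunit ribosomal proteins fell and 0 rose, with a median log2 change of -0.33 (camera adjusted p = 9.65e-09; adjusted p = 0.359 with an estimated correlation), as did 22 of 41 small-subunit ones, of which 5 rose (adjusted p = 0.00168; adjusted p = 0.548 with an estimated correlation). In co-cultured cells 5 of the 55 fell and 2 rose, and the difference of effects was called downward for 13 and upward for 0 (adjusted p = 2.06e-10; adjusted p = 0.2 with an estimated correlation). With a term for the replicate-1 arrays 3 of the 55 fell and 0 rose in co-culture, and in the other 8 arrays alone 4 were called downward for the difference. Under median centring 3 fell in co-culture. The medians of these families in RAS cells stayed negative under quantile normalization (-0.33 and -0.33) and median centring (-0.29 and -0.21). Of their mitochondrial counterparts, 22 of 48 large-subunit genes rose and 2 fell in RAS cells (adjusted p = 0.0201; adjusted p = 0.548 with an estimated correlation), while 9 of 26 small-subunit genes rose and 3 fell with no shift of the family (adjusted p = 0.539). Both were shifted upward in co-culture with vector cells, which shares its controls with the RAS effect (adjusted p = 0.00889 and 0.00179; adjusted p = 0.671 and 0.474 with an estimated correlation), with 0 and 2 members called. The median of the mitochondrial large-subunit genes in RAS cells was 0.20, with 0.12 under quantile normalization, where 17 rose and 6 fell, and 0.24 under median centring. In the 8 arrays with numbers 2 and 3, 14 rose and 1 fell. Ribosomal protein genes have near-identical pseudogene copies elsewhere in the genome, so single members are uncertain.

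The clustered beta protocadherins, adhesion molecules best known from neurons, fell as a family. In RAS cells 14 of 18 fell and 0 rose, with a median of -0.90 (adjusted p = 5e-08; adjusted p = 0.113 with an estimated correlation), and in co-cultured cells 10 fell and 0 rose, with a median of -0.44 (adjusted p = 0.000102; adjusted p = 0.422 with an estimated correlation). With vector cells 4 fell and 0 rose, with a median of -0.21 (adjusted p = 0.0352; adjusted p = 0.671 with an estimated correlation). The difference of effects was called downward for 9 and upward for 0 (adjusted p = 4.37e-05; adjusted p = 0.2 with an estimated correlation), and for 5 in the 8 arrays with numbers 2 and 3. The median in RAS cells was -0.86 under both quantile normalization and median centring. These genes resemble each other in sequence, so single members are uncertain, and their mean log2 signal was 3.39.

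Beyond CEMIP, MEDAG and ABI3BP, the 103 genes called in opposite directions included, chosen after their values were seen, FLRT3 (2.05 with RAS, -0.98 in co-culture), the interferon-induced IFI6 (1.87 and -0.77), AKR1C1 (1.48 and -0.79) and CD248 (0.36 and -1.63). The 2 effects have different controls, so opposite directions can include a gap between the controls, as for CEMIP.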
